A study of Mus musculus with 13 samples.

How the data were processed

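The labels describe 13 samples of mouse femoral bone marrow, from controls and from mice at 4, 9, 12, 15 or 48 h after phlebotomy. Per the labels' protocols, RNA was taken with Trizol and cleaned on RNeasy columns, then amplified and labelled with a whole transcript cDNA kit for Affymetrix Mouse Gene 1.0 ST arrays, which use 1 colour. The deposited value table holds 1 column per array of log2 levels, made by the authors with RMA per the submitters' processing notes; the version of RMA is not given in the sources used here. The scanner files were not used here. Which arrays were normalized together is not given in the sources used here.

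Each sample was placed in its group by the time its labels give. The numbers in the titles run in 2 series, of 10 and 3 arrays, and the values of the smaller series differ from those of the larger in level and in how often they repeat, so the series was treated as a batch. Levels are compared only within a series. Replicate numbers follow the order of the samples and pair nothing. The labels do not say whether the replicates of a group are separate animals, so the p-values measure the spread between these samples, which may be technical. The 4 h group has 1 mouse, which was assumed to vary like the other groups. The labels used here give neither the hour of day of collection nor a sham puncture for the controls.

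The table has 35557 probe sets. By the platform annotation 21789 of them have exactly 1 gene symbol, 1621 several, and 12147 are not listed with a gene here; no gene was named from a probe set with several. Symbols were updated through the Entrez identifier for 21698 of the probe sets with 1 gene. Where a gene had more than 1 probe set (999 genes), the one with the highest mean over all arrays stood for it, which left 19938 genes, 19856 of them with a symbol taken from the Entrez identifier. Gdf15 is not named by this annotation and was not analysed here.

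From these log2 values 1 linear model was fitted to all 13 arrays with limma 3.58.1 in R 4.3.3, with 6 groups and a fixed term for the series, which left 6 residual degrees of freedom, and moderated with eBayes (4.62 prior degrees of freedom). The 7 contrasts were each time against control, the mean of 9, 12 and 15 h against control, and 48 h against that mean. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over 19938 genes. The 31 gene lists, of pathways and of cell types that marrow or its surroundings could hold, were written from textbook knowledge. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists of each contrast, and needed at least 5 measured genes. Another 6 lists, of small intestine (86 genes, 80 measured), liver (83 genes, 77 measured) and 4 groups of enzymes and chaperones, were written after the called genes had been seen and were adjusted among themselves. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

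The groups, the contrasts, the 31 lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule named, for each contrast, the 6 largest rises and the 6 largest falls among genes past the threshold whose arrays all lay beyond every array of the other group, judged within each series; predicted genes and small nucleolar RNAs were skipped there. It also named up to 4 members past the threshold, with the smallest p, of each list that camera called or that had at least 3 members past it, and Erfe, Twsg1, Hamp, Tfrc and Alas2 against control.

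The fit was tested on simulated data for 19938 genes, made from the fitted control level, the fitted series shift and each gene's moderated spread. On all arrays but the controls, 50 genes were changed at each of 4 sizes. The noise was normal, independent between genes and equal on all arrays. Repeated values, correlated genes and arrays with transcripts of other tissues were absent, so the shares hold for such data only. For the mean of 9, 12 and 15 h against control it recovered 96% of genes changed by log2 0.5, 98% at 1 and 100% at 1.5 and at 2. For 4 h against control these shares were 32%, 94%, 100% and 100%, for 9 h 86%, 96%, 100% and 100%, for 12 h 72%, 96%, 100% and 100%, for 15 h 70%, 96%, 100% and 100%, and for 48 h 64%, 96%, 100% and 100%. Of the calls made, unchanged genes were 4 of 201 for the mean of 9, 12 and 15 h, 14 of 177 at 4 h, 7 of 198 at 9 h, 9 of 193 at 12 h, 9 of 192 at 15 h and 7 of 187 at 48 h. The number of arrays limits the precision.

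The alternatives left out the series term, made it a random block, used the larger series or the contrast's groups alone, left out dim genes, tested every probe set, normalized or centred the arrays again, let the variance follow the level with robust moderation, weighted the arrays, and left out each array in turn; list tests under other fits used cameraPR on z values from the fit's p. Alternatives chosen after the data were seen used the smaller series alone, left out the marker genes of intestine, liver and muscle, or left out the 4 h and 48 h arrays. Probe sets with several genes or none listed were tested apart and entered none of the counts of genes.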

Results

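RNA from 13 bone marrow samples of male C57BL/6 mice, 6 weeks old, was measured on Affymetrix Mouse Gene 1.0 ST arrays, 1 array per sample, and each sample is written of here as 1 mouse. Phlebotomised mice lost 500 µL of blood through a retro-orbital puncture. Their femurs were taken 4 h (n = 1), 9 h (n = 3), 12 h (n = 2), 15 h (n = 2) or 48 h (n = 2) later. A further 3 mice were controls. Loss of blood raises erythropoietin, and the erythroid precursors that answer to it make signals that lower hepcidin, the liver hormone that limits iron uptake. The comparisons asked which marrow transcripts changed at each time. Among them are Erfe (erythroferrone, a hormone of erythroid precursors that lowers hepcidin) and Twsg1 (a secreted protein that binds bone morphogenetic proteins), both studied as such signals.

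The numbers in the sample titles run in 2 series, a larger one of 10 arrays and a smaller one of 3 (control replicate 3 and 9 h replicates 1 and 2). The median log2 level was 7.01 in the larger series and 7.8 in the smaller. In the smaller series 62.3% of probe sets had the same value on at least 2 of the 3 arrays, against at most 0.110% for any 3 arrays of the larger series, and 81.7% of the variance over all genes lay between the series. Each comparison therefore carried a term for the series, and no level is set across them. Arrays of 1 group within 1 series correlated at 0.993 to 0.999 over all genes. In the larger series the 4 h array lay farthest from the others on the first principal component, which held 31.7% of the variance there. The number of arrays limits the precision of every value: the median standard error of a log2 fold change ran from 0.07 for the 3 middle times together to 0.12 at 4 h.

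Changes are given as log2 fold change ± standard error from 1 limma fit to 19938 genes, with p adjusted by the Benjamini-Hochberg method over those genes and a threshold of 0.05. The groups of genes are 31 lists tested against all other genes with camera at a preset correlation of 0.01. The list named for globins and the red cell membrane held no measured globin, so its values are those of other red cell genes. With a correlation estimated from the residuals, camera called 0 of the 31 lists in each of the 7 comparisons, while 0 to 5 lists per comparison had an unadjusted p under 0.05. fry tests whether a list's genes move one way on balance and does not compare them with other genes. It called 0 to 7 lists per comparison.

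At 4 h after phlebotomy Erfe was higher, by log2 0.81 ± 0.10 or 1.76-fold (adjusted p = 0.00105), in the single mouse against 3 controls. Cish, an inhibitor of cytokine signalling that STAT5 induces, rose by 1.43 ± 0.22 (adjusted p = 0.00409). Socs3, another feedback inhibitor of cytokine receptors, rose by 0.59 ± 0.10, and Id1, a target of bone morphogenetic protein signalling, by 0.75 ± 0.15. The largest rises were those of genes of gut epithelium. Defa24, a defensin of Paneth cells, rose by 5.32 ± 0.22 (adjusted p = 1.02e-07), and Reg3g and Reg3b, antimicrobial lectins of the intestine, by 4.73 ± 0.13 and 4.44 ± 0.27. They were followed by Lypd8 at 4.59 ± 0.13, Apoa1, an apolipoprotein of liver and intestine, at 4.43 ± 0.19, and Muc3, an intestinal mucin, at 4.36 ± 0.18. In all, 347 genes rose and 50 fell.

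Of 16 measured erythropoietin and STAT5 target genes at 4 h, 4 rose and 12 did not pass, and 5 rose when adjusted over the list alone. Camera placed this list upward (median 0.07, adjusted p = 0.00640; adjusted p = 0.721 with an estimated correlation). Of 18 hepcidin regulators and genes of the BMP pathway 2 rose, Erfe and Id1, with 2 adjusted over the list alone. The median was 0.18 (camera adjusted p = 0.0322, adjusted p = 0.721 with an estimated correlation). None of 29 mitosis genes passed over all genes and 11 were lower when adjusted over the list alone (median −0.30, camera adjusted p = 7.66e-11). For 33 DNA replication genes these counts were 0 and 8 lower (median −0.28, camera adjusted p = 3.99e-09). For 22 genes of globins and the red cell membrane they were 0 and 1 lower (median −0.32, camera adjusted p = 3.52e-07), and for 21 interferon response genes 0 and 9 lower (median −0.49, camera adjusted p = 5.26e-08). Each of these 4 lists had an adjusted p = 0.721 with an estimated correlation. Without control replicate 2 the mean shift went from −0.36 to −0.20 for globins and the red cell membrane, from −0.31 to −0.19 for mitosis and from −0.48 to −0.31 for the interferon response. Of 24 B-lineage markers 1 fell, Ebf1, a transcription factor of early B cells, by 0.57 ± 0.11 (adjusted p = 0.0277), with 2 adjusted over the list alone. The median was −0.10 (camera adjusted p = 0.0415, adjusted p = 0.740 with an estimated correlation). Camera lost the erythropoietin and STAT5 list without control replicate 1 (adjusted p = 0.0523) and the hepcidin and BMP list without control replicate 3 or 9 h replicate 3 (adjusted p = 0.0732). It lost the B-lineage list without control replicate 1 (adjusted p = 0.0769), control replicate 3 or 9 h replicate 3 (adjusted p = 0.145), or either 12 h array (adjusted p = 0.0512).

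Camera called 4 further lists at 4 h, each with 0 genes past the threshold over all genes and an adjusted p = 0.721 with an estimated correlation. Upward were 25 hypoxia-inducible and glycolysis genes (3 higher adjusted over the list alone, median 0.19, camera adjusted p = 0.00216) and 24 genes of MYC and ribosome biogenesis (1 higher, median 0.22, camera adjusted p = 0.00733). Downward, with 0 adjusted over the list alone, were 17 erythroid transcription factors (median −0.29, camera adjusted p = 4.78e-05) and 15 megakaryocyte and platelet markers (median −0.26, camera adjusted p = 0.00566). The MYC call was lost without control replicate 1 (adjusted p = 0.0804). Without control replicate 2 the mean shift went from 0.17 to 0.11 for the hypoxia list and from −0.28 to −0.16 for the erythroid transcription factors.

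Predicted genes aside, the largest falls at 4 h were those of Stxbp4 (−0.99 ± 0.22), Prame (−0.95 ± 0.17), Cd59b, a membrane inhibitor of complement (−0.89 ± 0.20), Stag3, a cohesin subunit of meiosis (−0.84 ± 0.16), Ifi207, of the interferon-inducible p200 family (−0.84 ± 0.13), and Zfp617 (−0.77 ± 0.13). Twsg1 (0.18 ± 0.12, adjusted p = 0.540), Hamp, the hepcidin gene (−0.16 ± 0.16, adjusted p = 0.689), Tfrc, the transferrin receptor (−0.01 ± 0.15, adjusted p = 0.984), and Alas2, the first enzyme of erythroid heme synthesis (−0.11 ± 0.10, adjusted p = 0.659), did not pass. Markers of other tissues stood beside all of these groups. Of 80 small intestine markers, a list written after the called genes had been seen and so no independent evidence of direction, 57 rose and 60 did so adjusted over the list alone. The median was 1.78 (camera adjusted p = 1.52e-89, adjusted p = 0.00081 with an estimated correlation). The 14 skeletal muscle markers had a median of 1.61 with 0 past the threshold over all genes or over the list alone (camera adjusted p = 1.75e-05; adjusted p = 0.721 with an estimated correlation). On the 4 h array the deposited log2 level of Reg3g was 12.3 against 7.61 and 7.54 in the controls of its series, and that of Fabp2, the fatty acid binding protein of the small intestine, 11.5 against 7.62 and 7.12.

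The spread at 4 h was taken from the other groups. Of the 17 named genes past the threshold 12 kept their call without each other array in turn, the 5 exceptions being Cd59b, Stxbp4, Id1, Ebf1 and Stag3, and the count of 397 genes ran from 293 without control replicate 2 to 1359 without control replicate 1. Of the 2 directions the falls varied most, from 13 to 566 in those 2 fits against 280 and 793 rises. In the larger series alone 266 genes rose and 9 fell, and with the groups of the contrast alone 199 and 0.

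**Figure D1:**
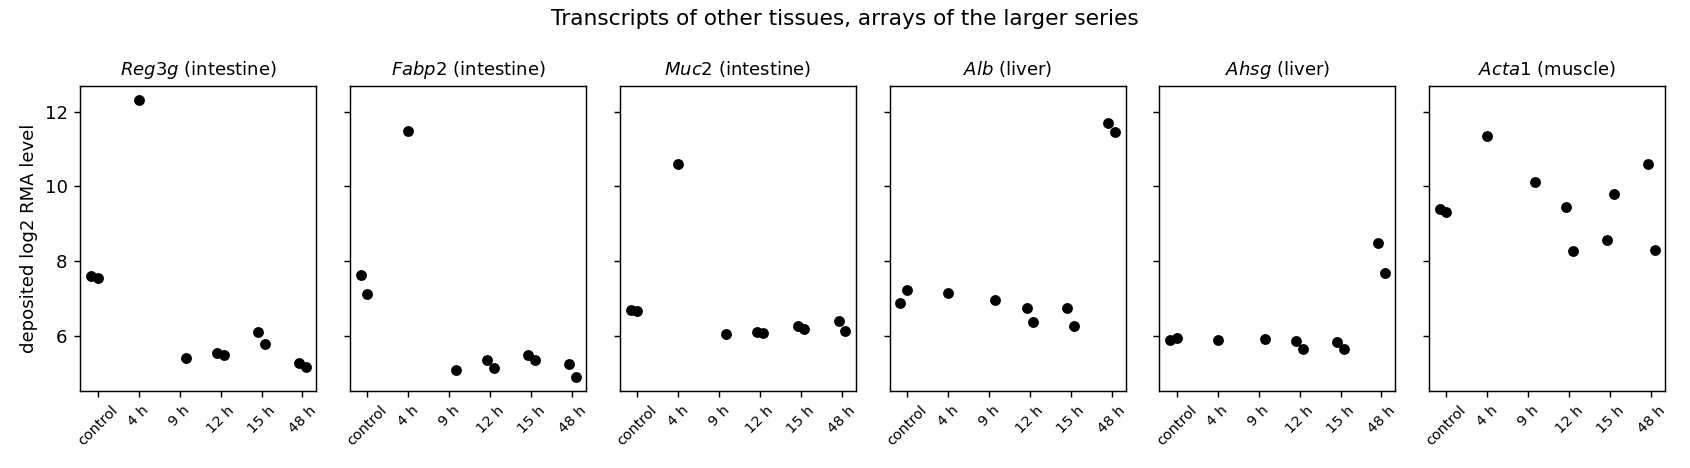
Deposited log2 level of 3 intestinal genes (Reg3g, Fabp2, Muc2), 2 liver genes (Alb, Ahsg) and 1 skeletal muscle gene (Acta1) on each array of the larger series, by hours after phlebotomy, with 1 point per array. Reg3g reached 12.3 on the 4 h array, and Alb 11.7 and 11.4 on the 48 h arrays.

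At 9 h after phlebotomy Cish rose by log2 2.40 ± 0.16 or 5.29-fold (adjusted p = 9.98e-05), in 3 mice against 3 controls. Erfe rose by 1.86 ± 0.08 or 3.64-fold (adjusted p = 1.35e-06). Fgf23, a hormone that lowers blood phosphate, rose by 1.66 ± 0.23, and Plek2, a pleckstrin protein of erythroblasts, by 1.16 ± 0.12. There were also rises of Noct (nocturnin), whose transcript cycles with the day, by 1.17 ± 0.15, Sema3a, a secreted semaphorin, by 1.14 ± 0.15, and Pim1, a kinase that STAT5 induces, by 0.85 ± 0.10 (adjusted p = 0.0127). The clock genes Nr1d1 (REV-ERB alpha) and Dbp fell by 1.11 ± 0.14 and 0.67 ± 0.10. With no hour of collection given, changes in clock and other genes at every time were not separated from time of day. The largest falls were those of the intestinal genes Reg3g (−2.21 ± 0.09, adjusted p = 1.35e-06), Reg3b (−2.13 ± 0.19) and Fabp2 (−2.03 ± 0.16), with Clca4b (−1.18 ± 0.14) and Fmo2, a flavin monooxygenase (−0.79 ± 0.12). In all, 10 genes rose and 9 fell.

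Of 16 erythropoietin and STAT5 target genes at 9 h, 3 rose (Cish, Erfe and Pim1), and 7 rose adjusted over the list alone. The median was 0.13 (camera adjusted p = 2.24e-09, adjusted p = 0.208 with an estimated correlation). The 24 genes of MYC and ribosome biogenesis held 0 genes past the threshold over all genes and 19 higher adjusted over the list alone. The median was 0.30 (camera adjusted p = 5.34e-22, adjusted p = 0.208 with an estimated correlation). For 17 heat shock proteins these counts were 0 and 6 higher. The median was 0.18 (camera adjusted p = 5.88e-07). For 21 interferon response genes they were 0 and 5 lower. The median was −0.30 (camera adjusted p = 2.72e-12). Of 17 circadian clock genes 2 fell, Nr1d1 and Dbp, with 1 higher and 3 lower adjusted over the list alone. The median was −0.08 (camera adjusted p = 0.00163). Each of these last 3 lists had an adjusted p = 0.340 with an estimated correlation. Twsg1 (−0.09 ± 0.09, adjusted p = 0.889), Hamp (−0.01 ± 0.12, adjusted p = 0.989), Tfrc (0.42 ± 0.11, adjusted p = 0.372) and Alas2 (−0.04 ± 0.07, adjusted p = 0.952) did not pass. Beside these groups, 4 of the 80 small intestine markers fell at 9 h, and 11 adjusted over the list alone (median −0.07; adjusted p = 0.0662 with an estimated correlation). Camera did not call the 77 liver markers at 9 h (median 0.00, adjusted p = 0.862), but 1 array stood out: the deposited log2 level of Alb was 9.68 on 9 h replicate 1, against 7.31 on 9 h replicate 2 and 7.74 in the control of the smaller series. Of 39 liver markers that differ within that series 26 were highest on 9 h replicate 1.

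Camera called other cell type lists at 9 h, each with 0 genes past the threshold over all genes and over the list alone. The 25 osteoblast, stromal and endothelial markers had a median of −0.24 (camera adjusted p = 3.91e-09, adjusted p = 0.340 with an estimated correlation). Their mean shift of −0.31 was −0.06 without 9 h replicate 3, −0.56 without control replicate 3 and −0.20 without control replicate 1. Camera called upward the 22 T and NK cell markers (median 0.13, adjusted p = 0.0011; adjusted p = 0.415 with an estimated correlation), the 13 antigen presentation genes (median 0.16, adjusted p = 0.0221; adjusted p = 0.548 with an estimated correlation) and the 20 mature neutrophil markers (median 0.05, adjusted p = 0.0496; adjusted p = 0.589 with an estimated correlation). All 3 of these upward calls were lost without 9 h replicate 3 (adjusted p = 0.479, 0.983 and 0.381), that of antigen presentation also without control replicate 2 (adjusted p = 0.123), and that of neutrophils in 7 of the 13 fits that each left out 1 array.

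Another 7 lists were called at 9 h, each with 0 genes past the threshold over all genes. Upward were 18 cholesterol synthesis genes (1 higher adjusted over the list alone, median 0.15, camera adjusted p = 8.38e-06; adjusted p = 0.340 with an estimated correlation) and 19 glucocorticoid response genes (2 higher, median 0.18, camera adjusted p = 0.000305; adjusted p = 0.340 with an estimated correlation). So were 22 inflammatory cytokines and NF-kB targets (0 higher, median 0.07, camera adjusted p = 0.0496; adjusted p = 0.568 with an estimated correlation). Downward, with 0 adjusted over the list alone, were 29 mitosis genes (median −0.06, camera adjusted p = 0.00422; adjusted p = 0.721 with an estimated correlation) and 22 genes of globins and the red cell membrane (median −0.06, camera adjusted p = 0.0378; adjusted p = 0.778 with an estimated correlation). So were 33 DNA replication genes (median −0.03, camera adjusted p = 0.0496; adjusted p = 0.721 with an estimated correlation) and 22 genes of iron uptake, storage and export (median −0.06, camera adjusted p = 0.0496; adjusted p = 0.340 with an estimated correlation). Without control replicate 2 the calls of the red cell membrane list (no globin measured), mitosis and DNA replication were lost. Their mean shifts of −0.068, −0.061 and −0.035 became 0.030, 0.0073 and 0.0093. Without control replicate 1 they were −0.17, −0.13 and −0.080. These 3 calls were lost without control replicate 3 as well, those of globins and DNA replication without 9 h replicate 1, and that of DNA replication without either 15 h array. The iron call was lost in 9 of the 13 fits and the inflammatory call in 8. Without 9 h replicate 3 the mean shift went from 0.16 to 0.078 for cholesterol synthesis and from 0.20 to 0.068 for the glucocorticoid response, and without control replicate 3 to 0.25 and 0.34.

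The 9 h comparison is the one that both series hold. Within the larger series (1 mouse at 9 h against 2 controls) Erfe rose by 1.96 and Cish by 2.48, with the spread taken from other groups. There 16 genes passed, 8 of them among the 19 of the full fit. In the smaller series (2 against 1) Erfe was higher by 1.76 and Cish by 2.33. That fit has 1 control and 1 residual degree of freedom, too few to read its calls as a response at 9 h. The list medians against the control of the smaller series were 0.16 and 0.14 for MYC and ribosome biogenesis and −0.37 and −0.11 for the interferon response, and in the larger series 0.45 and −0.37. Without 9 h replicate 3 the mean shift went from 0.28 to 0.17 for MYC and ribosome biogenesis and from 0.19 to 0.11 for heat shock proteins. Without control replicate 2 it went from −0.30 to −0.20 for the interferon response, and without control replicate 3 the circadian call was lost (adjusted p = 0.0631). Of the 14 named genes past the threshold 5 (Cish, Erfe, Fabp2, Reg3b and Reg3g) kept their call without each array in turn, and the count of 19 genes ran from 5 without 9 h replicate 3 to 75 without control replicate 3.

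At 12 h Cish was up by log2 1.77 ± 0.17 (adjusted p = 0.00347) and Erfe by 1.43 ± 0.08 or 2.70-fold (adjusted p = 4.31e-05), in 2 mice against 3 controls. Plek2 rose by 1.30 ± 0.14, Sema3a by 1.24 ± 0.16, Pim1 by 0.81 ± 0.11 and Adamts5, a protease of cartilage matrix, by 0.80 ± 0.12. The mitochondrial chaperonins Hspe1 and Hspd1 rose by 0.79 ± 0.11 and 0.58 ± 0.09, and Nop58, a protein of the particles that modify ribosomal RNA, by 0.57 ± 0.08 (adjusted p = 0.0272). In all, 17 genes rose and 4 fell, the falls being Reg3g (−2.07 ± 0.10), Fabp2 (−2.04 ± 0.18), Reg3b (−1.93 ± 0.21) and Clca4b (−1.69 ± 0.15).

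Of 16 erythropoietin and STAT5 target genes at 12 h, 3 rose, and adjusted over the list alone 7 were higher and 1 lower. The median was 0.19 (camera adjusted p = 2.59e-05, adjusted p = 0.309 with an estimated correlation). Of 24 genes of MYC and ribosome biogenesis 1 rose, Nop58, and 11 adjusted over the list alone. The median was 0.24 (camera adjusted p = 3.52e-14, adjusted p = 0.295 with an estimated correlation). Of 17 heat shock proteins 2 rose, Hspe1 and Hspd1, and 6 adjusted over the list alone. The median was 0.16 (camera adjusted p = 2.59e-05, adjusted p = 0.309 with an estimated correlation). None of 21 interferon response genes passed over all genes and 17 were lower adjusted over the list alone. The median was −0.54 (camera adjusted p = 1.35e-14, adjusted p = 0.309 with an estimated correlation). The 15 megakaryocyte and platelet markers held 0 genes past the threshold and 1 lower adjusted over the list alone. The median was −0.26 (camera adjusted p = 9.23e-06, adjusted p = 0.514 with an estimated correlation). Twsg1 (0.23 ± 0.10, adjusted p = 0.346), Hamp (−0.21 ± 0.13, adjusted p = 0.516), Tfrc (0.53 ± 0.12, adjusted p = 0.115) and Alas2 (−0.10 ± 0.08, adjusted p = 0.615) did not pass. Of the 80 small intestine markers 3 fell at 12 h, and 20 adjusted over the list alone (median −0.17; adjusted p = 0.0478 with an estimated correlation). The 14 skeletal muscle markers held 0 genes past the threshold by either count (median −0.67, camera adjusted p = 0.0151; adjusted p = 0.732 with an estimated correlation). This call was lost without 12 h replicate 2 (adjusted p = 0.433) and without control replicate 3 or 9 h replicate 3 (adjusted p = 0.126), and the mean shift of −0.69 was −1.06 without 12 h replicate 1. The 24 B-lineage markers held 0 past and 2 lower adjusted over the list alone (median −0.20, camera adjusted p = 0.000384; adjusted p = 0.635 with an estimated correlation). The mean shift of the megakaryocyte list went from −0.27 to −0.16 without 12 h replicate 1.

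Another 6 lists were called at 12 h, each with 0 genes past the threshold over all genes. Upward were 22 genes of ATF4 and the unfolded protein response (2 higher adjusted over the list alone, median 0.13, camera adjusted p = 0.000656; adjusted p = 0.226 with an estimated correlation) and 18 cholesterol synthesis genes (2 higher, median 0.18, camera adjusted p = 5.56e-05; adjusted p = 0.490 with an estimated correlation). Downward were 17 circadian clock genes (7 lower adjusted over the list alone, median −0.22, camera adjusted p = 0.000384; adjusted p = 0.309 with an estimated correlation) and 17 erythroid transcription factors (0 lower, median −0.17, camera adjusted p = 0.00217; adjusted p = 0.732 with an estimated correlation). So were 13 antigen presentation genes (1 lower, median −0.12, camera adjusted p = 0.0260; adjusted p = 0.635 with an estimated correlation) and 19 stem and progenitor markers (0 lower, median −0.10, camera adjusted p = 0.0328; adjusted p = 0.514 with an estimated correlation). The erythroid call was lost without control replicate 2 (mean shift −0.027 against −0.14, adjusted p = 0.404) or 12 h replicate 1 (adjusted p = 0.125), and the shift was −0.29 without control replicate 1. The antigen call was lost in 4 of the 13 fits that each left out 1 array, and its mean shift of −0.12 was −0.20 without control replicate 2. The stem cell call was lost without control replicate 1 (adjusted p = 0.503) or 12 h replicate 2 (adjusted p = 0.134), and its mean shift of −0.091 was −0.15 without control replicate 2.

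Within the larger series alone, which holds both 12 h arrays, 10 genes passed, Erfe at 1.47 and Cish at 1.80 among them. Of the 13 named genes past the threshold 5 (Cish, Clca4b, Erfe, Fabp2 and Reg3g) kept their call without each array in turn, and the count of 21 genes ran from 6 without 12 h replicate 1 to 414 without control replicate 1.

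At 15 h Cish was raised by log2 1.94 ± 0.17 (adjusted p = 0.00143) and Erfe by 1.72 ± 0.08 or 3.29-fold (adjusted p = 1.32e-05), in 2 mice against 3 controls. Mmp13, a collagenase of bone, had the largest rise at 2.09 ± 0.26 (adjusted p = 0.0109). Podxl, a sialomucin of early erythroid cells and endothelium, rose by 1.35 ± 0.12, Plek2 by 1.52 ± 0.14, Fgf23 by 1.54 ± 0.26, Pim1 by 0.88 ± 0.11 and Mt1, a metallothionein, by 0.64 ± 0.10. The nucleolar proteins Nop58, Npm1, Gnl3 and Wdr12, which serve the making of ribosomes, rose by 0.56 ± 0.08, 0.51 ± 0.08, 0.55 ± 0.09 and 0.62 ± 0.10. In all, 42 genes rose and 9 fell.

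Of 16 erythropoietin and STAT5 target genes at 15 h, 4 rose, and 9 adjusted over the list alone. The median was 0.34 (camera adjusted p = 1.52e-07, adjusted p = 0.211 with an estimated correlation). Of 24 genes of MYC and ribosome biogenesis 5 rose, and 17 adjusted over the list alone. The median was 0.36 (camera adjusted p = 8.49e-19, adjusted p = 0.155 with an estimated correlation). Of 17 heat shock proteins 2 rose, Hspe1 by 0.73 ± 0.11 and Hspd1 by 0.54 ± 0.09, and 5 adjusted over the list alone. The median was 0.19 (camera adjusted p = 1.17e-05, adjusted p = 0.390 with an estimated correlation). The 18 cholesterol synthesis genes held 0 past the threshold over all genes and 4 higher adjusted over the list alone. The median was 0.23 (camera adjusted p = 3.27e-05, adjusted p = 0.583 with an estimated correlation). The 21 interferon response genes held 0 by either count. The median was −0.26 (camera adjusted p = 1.9e-05, adjusted p = 0.583 with an estimated correlation). The largest falls were those of Fabp2 (−1.86 ± 0.18), Reg3b (−1.69 ± 0.21), Reg3g (−1.65 ± 0.10), Clca4b (−1.11 ± 0.15), Zg16, a lectin of goblet cells (−1.10 ± 0.10), and Fmo2 (−0.94 ± 0.13). Twsg1 (0.22 ± 0.10, adjusted p = 0.398), Hamp (−0.20 ± 0.13, adjusted p = 0.552), Tfrc (0.41 ± 0.12, adjusted p = 0.228) and Alas2 (−0.15 ± 0.08, adjusted p = 0.458) did not pass. Of the 80 small intestine markers 4 fell at 15 h, and 22 adjusted over the list alone (median −0.18; adjusted p = 0.0381 with an estimated correlation).

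Beside the rises of Mmp13, Fgf23 and Podxl at 15 h, the 25 osteoblast, stromal and endothelial markers held 0 past the threshold over all genes and 2 higher adjusted over the list alone. Their median was 0.21 (camera adjusted p = 0.00047, adjusted p = 0.583 with an estimated correlation). That call was lost without 15 h replicate 2 (adjusted p = 0.0604), and the mean shift of 0.24 was 0.43 without control replicate 1 and 0.16 without control replicate 3 or 9 h replicate 3. The interferon call was lost without control replicate 2 (mean shift −0.10 against −0.27, adjusted p = 0.0718), and the shift was −0.43 without control replicate 1. For cholesterol synthesis it went from 0.20 to 0.13 without 15 h replicate 2.

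Other cell type lists went downward at 15 h, each with 0 genes past the threshold over all genes. The 15 megakaryocyte and platelet markers held 1 lower adjusted over the list alone (median −0.21, camera adjusted p = 0.00167; adjusted p = 0.583 with an estimated correlation), and the 14 promyelocyte granule markers 1 (median −0.08, camera adjusted p = 0.0357; adjusted p = 0.583 with an estimated correlation). For the others that count was 0: 13 antigen presentation genes (median −0.13, camera adjusted p = 0.00854; adjusted p = 0.583 with an estimated correlation), 17 mast cell, basophil and eosinophil markers (median −0.15, camera adjusted p = 0.00924; adjusted p = 0.583 with an estimated correlation), 22 T and NK cell markers (median −0.10, camera adjusted p = 0.0357; adjusted p = 0.583 with an estimated correlation) and 24 B-lineage markers (median −0.07, camera adjusted p = 0.0463; adjusted p = 0.667 with an estimated correlation). Only the megakaryocyte and mast cell calls were kept in all 13 fits that each left out 1 array; the mean shift of the first was −0.18, −0.27 without control replicate 1 and −0.12 without control replicate 3 or 9 h replicate 3. The antigen and T and NK cell calls were each lost in 4 fits, and the promyelocyte call without control replicate 1 or 15 h replicate 1. The B-lineage call was lost in 9 fits, and its mean shift of −0.088 was 0.053 without 15 h replicate 1 and −0.23 without 15 h replicate 2.

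The 29 mitosis genes were also called downward at 15 h, with 0 past the threshold by either count (median −0.09, camera adjusted p = 0.00206; adjusted p = 0.667 with an estimated correlation). The mean shift of −0.11 was −0.22 without control replicate 1 and 0.0093 without control replicate 2, where the call was lost. Upward were 22 genes of ATF4 and the unfolded protein response, with 0 past the threshold and 2 higher adjusted over the list alone (median 0.15, camera adjusted p = 0.000497; adjusted p = 0.155 with an estimated correlation). Of 19 glucocorticoid response genes 1 rose, Mt1, and 2 adjusted over the list alone (median 0.16, camera adjusted p = 0.00854; adjusted p = 0.583 with an estimated correlation). This call was lost without 15 h replicate 2 (mean shift 0.076 against 0.22, adjusted p = 0.504) or control replicate 1 (adjusted p = 0.0550), and the shift was 0.36 without 15 h replicate 1. Of 18 hepcidin regulators and genes of the BMP pathway 1 rose, Erfe, with 1 higher and 1 lower adjusted over the list alone (median 0.07, camera adjusted p = 0.0449; adjusted p = 0.583 with an estimated correlation), and the call was lost in 8 of the 13 fits.

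Within the larger series alone, which holds both 15 h arrays, 22 genes passed, Erfe at 1.75 and Podxl at 1.40 among them. Of the 20 named genes past the threshold 6 (Cish, Erfe, Plek2, Podxl, Reg3g and Zg16) kept their call without each array in turn, and the count of 51 genes ran from 6 without 15 h replicate 2 to 505 without control replicate 1.

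**Figure D2:**
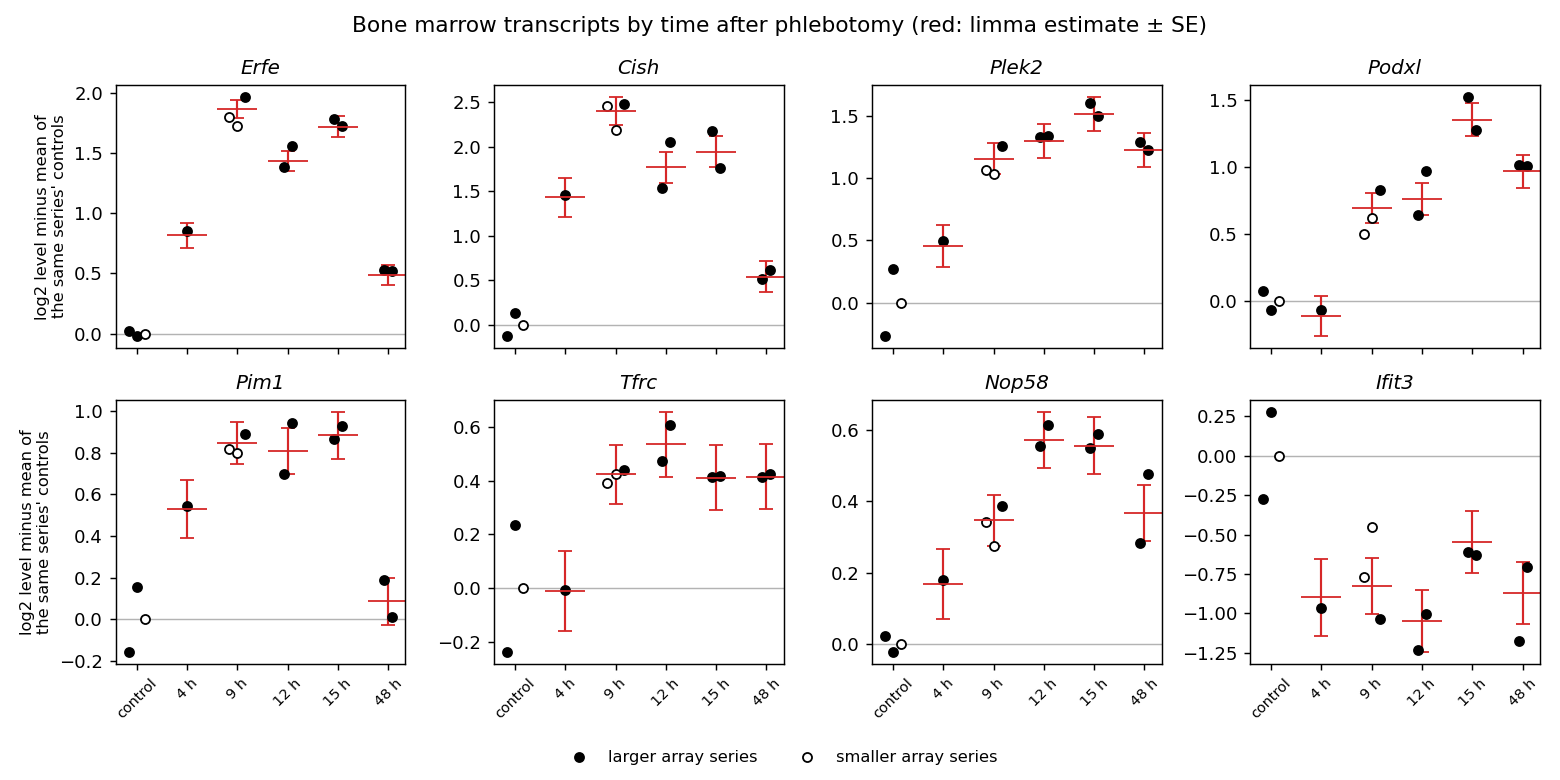
Log2 level of 8 genes on each array minus the mean of the controls of the same series, by hours after phlebotomy; filled points are the larger series, open points the smaller, and red bars the limma estimate ± standard error. The estimate for Erfe was 0.81 at 4 h, 1.86 at 9 h, 1.43 at 12 h, 1.72 at 15 h and 0.49 at 48 h.

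Taking 9, 12 and 15 h together (7 mice against 3 controls), Cish was raised by log2 2.04 ± 0.13 or 4.11-fold (adjusted p = 6.15e-05) and Erfe by 1.67 ± 0.06 or 3.18-fold (adjusted p = 4.70e-07). Plek2 rose by 1.32 ± 0.10, Podxl by 0.94 ± 0.09 and Pim1 by 0.85 ± 0.08. Fgf23 rose by 1.40 ± 0.19, Mmp13 by 1.37 ± 0.19 and Sema3a by 1.22 ± 0.12. Tfrc, through which erythroid precursors take up iron, rose by 0.46 ± 0.09 (adjusted p = 0.0453). In all, 130 genes rose and 27 fell.

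Of 24 genes of MYC and ribosome biogenesis 7 rose over these times, among them Nop58 (0.49 ± 0.06), Npm1 (0.42 ± 0.06), Gnl3 (0.47 ± 0.06) and Nop16 (0.51 ± 0.07), and 21 adjusted over the list alone. The median was 0.30 (camera adjusted p = 4.49e-24, adjusted p = 0.0947 with an estimated correlation). Of 16 erythropoietin and STAT5 target genes 7 rose, and adjusted over the list alone 7 were higher and 1 lower. The median was 0.20 (camera adjusted p = 1.86e-08, adjusted p = 0.174 with an estimated correlation). Of 17 heat shock proteins 3 rose, Hspe1 (0.66 ± 0.08), Hspd1 (0.50 ± 0.06) and Hsp90aa1 (0.37 ± 0.06), and 10 adjusted over the list alone. The median was 0.18 (camera adjusted p = 1.02e-07, adjusted p = 0.226 with an estimated correlation). Of 18 cholesterol synthesis genes 2 rose, Idi1 (0.48 ± 0.08) and Msmo1 (0.35 ± 0.06), and 8 adjusted over the list alone. The median was 0.19 (camera adjusted p = 2.4e-07, adjusted p = 0.269 with an estimated correlation). Of 22 genes of ATF4 and the unfolded protein response 1 rose, Asns, the asparagine synthetase (0.54 ± 0.09), and 4 adjusted over the list alone. The median was 0.09 (camera adjusted p = 0.000467, adjusted p = 0.0947 with an estimated correlation). Of 19 glucocorticoid response genes 2 rose, and 2 adjusted over the list alone (median 0.12, camera adjusted p = 0.0014; adjusted p = 0.528 with an estimated correlation); one was Mt1 (0.46 ± 0.07).

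Of 21 interferon response genes 2 fell at 9 to 15 h, Ifit3 (−0.81 ± 0.14) and Dhx58 (−0.43 ± 0.07), both of the antiviral response, and 12 adjusted over the list alone. The median was −0.34 (camera adjusted p = 5.14e-15, adjusted p = 0.269 with an estimated correlation). Of 17 circadian clock genes 1 fell, Dbp (−0.60 ± 0.08), and 6 adjusted over the list alone. The median was −0.15 (camera adjusted p = 0.000785, adjusted p = 0.269 with an estimated correlation). Of 15 megakaryocyte and platelet markers 1 fell, Gp9, a subunit of the platelet receptor for von Willebrand factor (−0.34 ± 0.06), and 1 adjusted over the list alone. The median was −0.17 (camera adjusted p = 0.000281, adjusted p = 0.688 with an estimated correlation). Without control replicate 2 the mean shift of the interferon list went from −0.38 to −0.22, and without control replicate 1 that of the clock list from −0.15 to −0.088. The megakaryocyte call was lost without control replicate 3 (adjusted p = 0.277), and its mean shift of −0.15 was −0.23 without control replicate 1. Camera also called downward the 17 erythroid transcription factors (median −0.10, adjusted p = 0.0218; adjusted p = 0.809 with an estimated correlation) and the 29 mitosis genes (median −0.08, adjusted p = 0.0012; adjusted p = 0.809 with an estimated correlation), each with 0 genes past the threshold over all genes and over the list alone. Without control replicate 2 both calls were lost and the mean shifts changed sign, from −0.076 to 0.026 and from −0.079 to 0.020. Without control replicate 1 they were −0.20 and −0.18. The first call was also lost without control replicate 3, 12 h replicate 1 or 15 h replicate 1 (adjusted p = 0.277, 0.0965 and 0.0506). Camera did not call the 17 heme synthesis genes (median −0.04, adjusted p = 0.385) or the 22 genes of globins and the red cell membrane (median −0.09, adjusted p = 0.0582). The largest falls were those of Reg3g (−1.97 ± 0.07), Fabp2 (−1.97 ± 0.13), Reg3b (−1.92 ± 0.16), Clca4b (−1.33 ± 0.11), Zg16 (−0.82 ± 0.08) and Fmo2 (−0.82 ± 0.09). Twsg1 (0.12 ± 0.07, adjusted p = 0.552), Hamp (−0.14 ± 0.09, adjusted p = 0.602) and Alas2 (−0.10 ± 0.06, adjusted p = 0.549) did not pass. Of the 80 small intestine markers 9 fell, and 23 adjusted over the list alone (median −0.13; adjusted p = 0.024 with an estimated correlation).

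Within the larger series alone 60 genes passed, with Erfe at 1.73, Cish at 2.08 and Nop58 at 0.51; Tfrc was 0.46 there (adjusted p = 0.179) and lost its call in 11 of the 13 fits that each left out 1 array (0.31 to 0.60). The count of 157 genes ran from 31 without control replicate 2 to 340 without control replicate 1, and 13 of the 31 named genes past the threshold kept their call in all 13 of those fits, among them Cish, Erfe, Plek2, Podxl, Pim1, Nop58 and Sema3a.

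**Figure D3:**
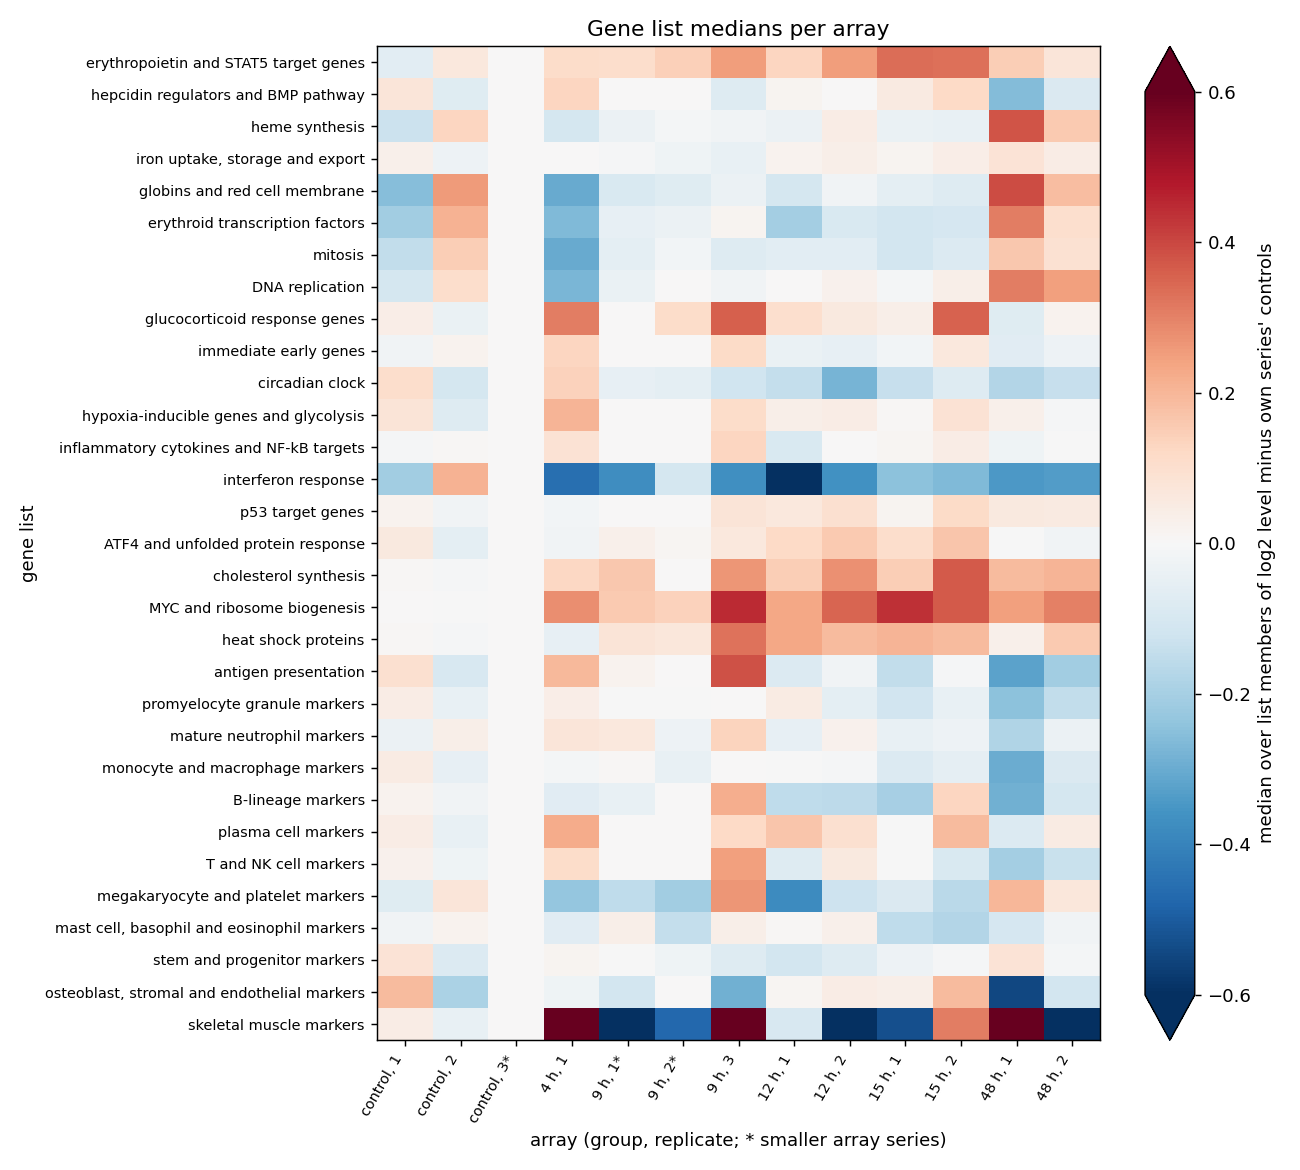
Median log2 level of the 31 gene lists on each of the 13 arrays, each gene taken minus the mean of the controls of the same series, as colours from −0.6 to 0.6; arrays of the smaller series carry an asterisk. The DNA replication list had medians of 0.31 and 0.24 on the 48 h arrays.

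At 48 h Erfe was raised by log2 0.49 ± 0.08 or 1.40-fold (adjusted p = 0.0387), in 2 mice against 3 controls. The largest rises were those of genes of liver. Alb, albumin, rose by 4.66 ± 0.54 or 25.2-fold (adjusted p = 0.00381) and Serpina1c, an alpha-1-antitrypsin, by 3.53 ± 0.35. They were followed by Fabp1, a fatty acid binding protein of liver and intestine, at 2.35 ± 0.30, Mup3, a major urinary protein, at 2.33 ± 0.14, Ahsg, fetuin A, at 2.18 ± 0.20, and Fgg, the gamma chain of fibrinogen, at 2.0 ± 0.13. The largest falls were those of Reg3b (−2.64 ± 0.21), Reg3g (−2.37 ± 0.10), Fabp2 (−2.20 ± 0.18), Clca4b (−1.50 ± 0.15), Sis, the intestinal sucrase-isomaltase (−0.79 ± 0.11), and Ifi207 (−0.78 ± 0.10). In all, 65 genes rose and 10 fell.

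None of 33 DNA replication genes passed over all genes at 48 h and 22 were higher adjusted over the list alone. The median was 0.28 (camera adjusted p = 2.35e-15, adjusted p = 0.261 with an estimated correlation). For 17 heme synthesis genes these counts were 0 and 8 higher (median 0.26, camera adjusted p = 3.44e-05; adjusted p = 0.308 with an estimated correlation), and for 22 genes of globins and the red cell membrane 0 and 2 higher. The median was 0.26 (camera adjusted p = 1.33e-06, adjusted p = 0.471 with an estimated correlation). For 24 genes of MYC and ribosome biogenesis they were 0 and 11 higher. The median was 0.24 (camera adjusted p = 4.5e-09, adjusted p = 0.261 with an estimated correlation). Camera called lists of white cells downward. The 13 antigen presentation genes held 0 past the threshold and 5 lower adjusted over the list alone (median −0.34, camera adjusted p = 4.18e-08; adjusted p = 0.261 with an estimated correlation). The 25 monocyte and macrophage markers held 0 and 6 lower (median −0.18, camera adjusted p = 4.5e-09; adjusted p = 0.261 with an estimated correlation), and the 24 B-lineage markers 0 and 4 lower. The median was −0.25 (camera adjusted p = 2.92e-08, adjusted p = 0.293 with an estimated correlation). For 14 promyelocyte granule markers both counts were 0. The median was −0.20 (camera adjusted p = 3.3e-07, adjusted p = 0.261 with an estimated correlation). They were 0 too for 22 T and NK cell markers (median −0.19, camera adjusted p = 1.92e-06; adjusted p = 0.261 with an estimated correlation), 20 mature neutrophil markers (median −0.12, camera adjusted p = 0.000322; adjusted p = 0.293 with an estimated correlation) and 25 osteoblast, stromal and endothelial markers (median −0.25, camera adjusted p = 0.00176; adjusted p = 0.533 with an estimated correlation). Interferon response genes held 0 past and 4 lower adjusted over the list alone. The median was −0.30 (camera adjusted p = 4.64e-09, adjusted p = 0.309 with an estimated correlation). Of 16 erythropoietin and STAT5 target genes 2 rose, and 4 adjusted over the list alone, and camera did not call the list (median 0.09, adjusted p = 0.069). Twsg1 (0.02 ± 0.10, adjusted p = 0.952), Hamp (0.20 ± 0.13, adjusted p = 0.529), Tfrc (0.42 ± 0.12, adjusted p = 0.175) and Alas2 (0.08 ± 0.08, adjusted p = 0.697) did not pass.

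Another 4 lists were called at 48 h, each with 0 genes past the threshold over all genes. Upward were 17 erythroid transcription factors (0 higher adjusted over the list alone, median 0.21, camera adjusted p = 0.00831; adjusted p = 0.582 with an estimated correlation) and 29 mitosis genes (0 higher, median 0.13, camera adjusted p = 0.00117; adjusted p = 0.582 with an estimated correlation). So were 18 cholesterol synthesis genes (2 higher, median 0.16, camera adjusted p = 0.000422; adjusted p = 0.385 with an estimated correlation), and downward were 17 circadian clock genes (0 lower, median −0.15, camera adjusted p = 0.000422; adjusted p = 0.261 with an estimated correlation).

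These list shifts at 48 h rested in part on single arrays. Without control replicate 1 the calls of the erythroid transcription factors (mean shift 0.034 against 0.18, adjusted p = 0.860) and of mitosis (0.0075 against 0.12, adjusted p = 0.960) were lost, and without control replicate 2 the shifts were 0.29 and 0.23. The call of the erythroid transcription factors was lost without 48 h replicate 1 too (adjusted p = 0.216). The shift of the clock list went from −0.15 to −0.085 without control replicate 1. In the larger series the 2 controls lay at −0.26 and 0.26 in the median of globins and the red cell membrane. The mean shift of that list was 0.26, 0.083 without control replicate 1 and 0.42 without control replicate 2, and for heme synthesis it went from 0.24 to 0.15 without control replicate 1. For the interferon response it went from −0.37 to −0.20 without control replicate 2. Without 48 h replicate 1 it went from −0.21 to −0.11 for monocytes and macrophages (−0.32 without 48 h replicate 2) and from −0.28 to −0.17 for the B lineage, and the neutrophil call was lost (adjusted p = 0.179). The stromal call was lost without that array (adjusted p = 0.675) or control replicate 1 (adjusted p = 0.503), and its mean shift of −0.23 was −0.38 without 48 h replicate 2.

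Markers of liver stood beside all of these groups at 48 h. Of 77 liver markers, a list written after the called genes had been seen and so no independent evidence of direction, 27 rose and 52 adjusted over the list alone. The median was 0.54 (camera adjusted p = 1.17e-40, adjusted p = 0.0263 with an estimated correlation). The deposited log2 level of Alb was 11.7 and 11.4 at 48 h against 6.87 and 7.23 in the controls of the larger series. Of the 80 small intestine markers 5 fell, and 14 adjusted over the list alone (median −0.11; adjusted p = 0.0633 with an estimated correlation), and the skeletal muscle list had medians of 1.01 and −0.98 on the 48 h arrays. Within the larger series alone 31 genes passed at 48 h, and Erfe was 0.52 there (adjusted p = 0.117) and lost its call in 8 of 13 fits that each left out 1 array (0.45 to 0.52, largest adjusted p = 0.189). Alb and Ifi207 lost their call without 48 h replicate 1 (adjusted p = 0.0657 and 0.0893), Sis lost its own without control replicate 1 (adjusted p = 0.0585), and the count of 75 genes ran from 31 without 48 h replicate 1 to 104.

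The difference between 48 h and the mean of 9, 12 and 15 h was tested directly, with 2 mice against 7. Cish, Erfe, Pim1 and Socs3 were lower at 48 h: Cish by log2 −1.50 ± 0.15 (adjusted p = 0.00114), Erfe by −1.18 ± 0.07 (adjusted p = 2.87e-05), Pim1 by −0.76 ± 0.10 and Socs3 by −0.47 ± 0.07. Gfi1b, a repressor needed for erythroid and platelet precursors, was higher by 0.77 ± 0.11, Aqp1, the water channel of the red cell membrane, by 0.57 ± 0.09, Tmem14c, a mitochondrial carrier of heme precursors, by 0.47 ± 0.08, and Urod, an enzyme of heme synthesis, by 0.46 ± 0.09. Lig1 and Clspn, of DNA replication, were higher by 0.39 ± 0.06 and 0.40 ± 0.08, and Gp9 by 0.38 ± 0.07. In all, 176 genes were higher and 19 lower at 48 h.

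Of 33 DNA replication genes 2 were higher at 48 h than at 9 to 15 h, and 27 adjusted over the list alone. The median was 0.23 (camera adjusted p = 3.04e-17, adjusted p = 0.239 with an estimated correlation). Of 22 genes of globins and the red cell membrane, with no globin among them, 1 was higher, and 12 adjusted over the list alone. The median was 0.33 (camera adjusted p = 8.38e-11, adjusted p = 0.308 with an estimated correlation). Of 17 heme synthesis genes 2 were higher, and 11 adjusted over the list alone. The median was 0.26 (camera adjusted p = 4e-07, adjusted p = 0.239 with an estimated correlation). Of 17 erythroid transcription factors 1 was higher, and 8 adjusted over the list alone. The median was 0.28 (camera adjusted p = 7.21e-06, adjusted p = 0.308 with an estimated correlation). Of 16 erythropoietin and STAT5 target genes 4 were lower, and 6 adjusted over the list alone. The median was −0.11 (camera adjusted p = 0.000206, adjusted p = 0.239 with an estimated correlation). Antigen presentation genes held 0 past and 7 lower adjusted over the list alone. The median was −0.24 (camera adjusted p = 2.92e-06, adjusted p = 0.239 with an estimated correlation). Sema3a (−0.88 ± 0.14), Ankrd36 (−0.76 ± 0.11) and Pgm3 (−0.58 ± 0.12) were also lower.

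For 48 h against 9 to 15 h camera also called 29 mitosis genes upward, with 0 past the threshold by either count (median 0.20, camera adjusted p = 1.56e-09; adjusted p = 0.308 with an estimated correlation). Of 15 megakaryocyte and platelet markers 1 was higher, Gp9, and 4 adjusted over the list alone (median 0.22, camera adjusted p = 2.76e-05; adjusted p = 0.308 with an estimated correlation). Both calls were kept in all 13 fits that each left out 1 array, and the mean shift of the megakaryocyte list went from 0.23 to 0.14 without 48 h replicate 1. Of 18 hepcidin regulators and genes of the BMP pathway 1 was lower, Erfe, and 2 adjusted over the list alone (median −0.12, camera adjusted p = 0.00146; adjusted p = 0.239 with an estimated correlation). The other 5 lists called downward held 0 past the threshold over all genes. For 22 genes of ATF4 and the unfolded protein response 1 was higher and 7 lower adjusted over the list alone (median −0.16, camera adjusted p = 0.00125; adjusted p = 0.239 with an estimated correlation), and for 17 heat shock proteins 2 and 5 (median −0.14, camera adjusted p = 0.00126; adjusted p = 0.308 with an estimated correlation). That count was 0 for 19 glucocorticoid response genes (median −0.22, camera adjusted p = 0.000206; adjusted p = 0.271 with an estimated correlation), 24 genes of MYC and ribosome biogenesis (median −0.05, camera adjusted p = 0.00744; adjusted p = 0.402 with an estimated correlation) and 22 inflammatory cytokines and NF-kB targets (median −0.06, camera adjusted p = 0.0423; adjusted p = 0.363 with an estimated correlation). Without 48 h replicate 1 the hepcidin, heat shock, glucocorticoid, MYC and inflammatory calls were lost (adjusted p = 0.0966, 0.0966, 0.0532, 0.323 and 0.289). The MYC call was lost without 9 h replicate 3 too (adjusted p = 0.238), and the inflammatory call in 5 of the 13 fits.

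Lists of other marrow cells were called downward at 48 h against 9 to 15 h, each with 0 genes past the threshold over all genes. The 25 monocyte and macrophage markers had 0 adjusted over the list alone (median −0.21, camera adjusted p = 2.85e-08; adjusted p = 0.239 with an estimated correlation). For 22 T and NK cell markers 2 were lower adjusted over the list alone (median −0.21, camera adjusted p = 4.13e-06; adjusted p = 0.239 with an estimated correlation), and for 24 B-lineage markers 3 (median −0.15, camera adjusted p = 1.14e-05; adjusted p = 0.308 with an estimated correlation). For 14 promyelocyte granule markers 4 were lower adjusted over the list alone (median −0.15, camera adjusted p = 1.13e-05; adjusted p = 0.239 with an estimated correlation), and for 20 mature neutrophil markers 1 (median −0.12, camera adjusted p = 3.65e-05; adjusted p = 0.239 with an estimated correlation). For 10 plasma cell markers 1 was lower adjusted over the list alone (median −0.12, camera adjusted p = 0.0091; adjusted p = 0.308 with an estimated correlation), and for 25 osteoblast, stromal and endothelial markers 0 (median −0.26, camera adjusted p = 0.000206; adjusted p = 0.363 with an estimated correlation). Without 48 h replicate 1 the B-lineage (adjusted p = 0.0555), neutrophil (adjusted p = 0.0525), plasma cell (adjusted p = 0.508) and stromal (adjusted p = 0.396) calls were lost. The mean shift of the monocyte list went from −0.20 to −0.092 without it, and without 48 h replicate 2 those of the monocyte, plasma cell and stromal lists were −0.30, −0.24 and −0.39. That of the plasma cell list went from −0.13 to −0.086 without 15 h replicate 2.

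The largest differences between 48 h and the earlier times were again liver transcripts, Alb at 4.80 ± 0.47, Serpina1c at 3.65 ± 0.31, Mup3 at 2.43 ± 0.12, Ahsg at 2.26 ± 0.17, Fabp1 at 2.22 ± 0.26 and Apoa1 at 2.06 ± 0.13. Of 77 liver markers 40 were higher, and 57 higher and 1 lower adjusted over the list alone. The median was 0.59 (camera adjusted p = 4.68e-50, adjusted p = 0.0294 with an estimated correlation). Within the larger series alone 57 genes passed, and without the marker genes of intestine, liver and muscle, a setting added after the data were seen, 94 did. Of the 20 named genes past the threshold 9 (Ahsg, Alb, Apoa1, Cish, Erfe, Fabp1, Mup3, Pim1 and Serpina1c) kept their call without each array in turn, Gfi1b lost it only without 48 h replicate 1, and the count of 195 genes ran from 32 without 48 h replicate 1 to 502 without control replicate 2.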

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

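The tests of the marrow response as a source at 4 h, in the controls and at 48 h, and the 3 on interferon response genes were chosen after the result was seen, and the marker lists were written then too; those of intestine and liver RNA on markers not yet looked at, and of other groupings of the arrays, were chosen before.

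Between 48 h and the mean of 9, 12 and 15 h, 195 genes differed in a direct limma test: Alb by 4.80, Serpina1c by 3.65, Mup3 by 2.43, Ahsg by 2.26, Fabp1 by 2.22 and Apoa1 by 2.06 among the higher ones on the log2 scale, and Cish by −1.50, Erfe by −1.18, Sema3a by −0.88, Ankrd36 by −0.76, Pim1 by −0.76, Pgm3 by −0.58 and Socs3 by −0.47 among the lower. Erythroid and replication genes differed too, Gfi1b by 0.77, Aqp1 by 0.57, Tmem14c by 0.47, Urod by 0.46, Clspn by 0.40, Lig1 by 0.39 and the platelet gene Gp9 by 0.38. Without 48 h replicate 1 the count was 32. Among the 1621 probe sets that name several genes, which were tested apart from the named genes, 15 passed at 9 to 15 h against control, 8 of them higher.

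Intestinal transcripts stood high in the 4 h array and, at a lower level, in all 3 controls. RNA from small intestine is a candidate source at 4 h: 48.3% of 58 markers not looked at beforehand lay more than 1 above each other array of the larger series on the log2 scale, against 0.802% of all genes and 0 in each of the other 9 arrays, but this fell short of the bound of 50% set for it. In the controls, the excess of those markers over the 12 h arrays followed the excess of the 4 h array with rho 0.45 across genes, which are not independent replicates (0.145 for other genes), between the bounds of 0.2 and 0.5. That control excess was 2.24% of the 4 h excess over the 20 highest markers, and 7 of the 80 markers lie above the median gene in marrow at 12 and 15 h. A response of marrow cells stays open as well, since 4 h has 1 mouse and all 3 controls lay above every 9 to 48 h array of their series, which both explanations allow.

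Liver transcripts stood high in both 48 h arrays and in 9 h replicate 1. A response of marrow cells at 48 h as the only source leaves the 9 h array out: of 39 liver markers that differ within the smaller series, 66.7% were highest in 9 h replicate 1, 3 in number in control replicate 3 and 0 in 9 h replicate 2, against 26.9% of all genes, a value that restates part of the pattern and bears on the 9 h array alone. RNA from liver may be a source and stays open, since 42.9% of 56 markers not looked at beforehand were higher in both 48 h arrays than in each other array of the larger series (5.85% of all genes), below the bound of 50% set for it. Alb reached 11.7 and 11.4 there, and 2 of the 77 markers lie above the median gene at 12 and 15 h. How the marrow was taken from the femurs was not examined, and a response of marrow cells in the 48 h arrays themselves stays open.

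Of 21 interferon response genes 2 fell at 9 to 15 h together and 0 at any single time, while the list was called downward (camera adjusted p = 5.14e-15; adjusted p = 0.269 with an estimated correlation). In the list mean every control lay above every phlebotomised array in 2 of 2 series. That argues against the array series as the cause, but the pattern was picked after its call in a fit that already held the series term. The margin was small for control replicate 1 (9.01 against 8.96 at 15 h), and the smaller series has 1 control. Phlebotomy or the time since it is a candidate explanation, with an exact two-sided p of 0.00741 over the 135 assignments of controls within the series, the smallest that design can give (adjusted p 0.0459 over the lists, where 5 lists reach that smallest p). That 1 control mouse with high levels carries part of the shift stays open: without control replicate 2 the mean shift at 9 to 15 h was −0.22 (standard error 0.11), against −0.51 and −0.40 without control replicates 1 and 3. An infection or housing difference was not tested.

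At 9 h against control, 2 of the 10 splits of the 6 arrays gave at least the real count of 19 genes. The highest other count was 19556, in the split that follows the array series, which points to the structure of the samples; the series term could not be fitted there, and the other splits gave 0. The splits are too few for a share under 0.05. At 9, 12 and 15 h together, 1 of 100 splits gave 157 genes, the real one, and the highest other count was 0. This argues against chance for that count, but the share can be no smaller than 1 of 100. Under other splits the real changes enter the spread, which lowers their counts. The count itself was 31 without control replicate 2 and 8 without the series term. In the splits 1 draw was left out because the series term could not be fitted.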

How the results depend on the processing

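The settings chosen after the data were seen are those named so above. All others were planned. Under settings that did not leave out single arrays, 1370 of 1693 values of named genes kept their direction and side of the threshold, 310 lost the call in the same direction and 13 reversed; of 1106 values of called lists 856 kept both and 250 lost the call. The fits that left out 1 array count repeated and unchanged ones too. There 1591 of 1942 gene values kept both, 344 were weaker, 1 stronger and 6 reversed. Of 1353 list values 1237 kept both, 111 were weaker and 5 reversed. For lists these counts go by the direction of camera, which sets a list against all other genes. The sign of the mean shift itself changed in 7 of the 1353 values, and without the series term in 22, of which 18 kept the call. The number of arrays limits every comparison, most of all 4 h with 1 mouse. No paired analysis was possible.

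Counts of genes, in the order 4, 9, 12, 15, 48 h, mean of 9 to 15 h, and 48 h against that mean, were 397, 19, 21, 51, 75, 157 and 195. Without the series term they were 78, 6, 5, 5, 11, 8 and 13, as the difference between the series then enters the spread; the median of all genes shifted by −0.26, 0.27, −0.27, −0.26 and −0.24 at the 5 times and by −0.16 for 48 h against the mean. With array weights they were 1852, 9, 4, 6, 14, 24 and 48. The weights were 14.5 and 10.2 for 9 h replicates 1 and 2, 3.10 for the 4 h array and 0.345 to 0.625 for the others. The 4 h array is fitted by its own group term, so its weight says nothing of its spread. With the series as a random block (correlation 0.963) the 6 counts from 9 h on were 32, 112, 81, 143, 252 and 335. The larger series alone has fewer arrays and lacks the repeated values of the smaller, and which of these mattered was not tested. The counts that moved there were 10 at 12 h, 22 at 15 h and 31 at 48 h. For the mean 60 passed, and for 48 h against it 57. The contrast's own groups alone gave 199, 3, 2, 9 and 13 at the 5 times and 462 for 48 h against the mean. Without dim genes 39 passed at 4 h, 59 at 12 h, 17 at 48 h and 259 for the mean. With the variance trend and robust moderation 65 passed at 12 h, 134 at 48 h and 243 for the mean. Without tissue marker genes 12 passed at 9 h, 21 at 48 h and 94 for 48 h against the mean, with fewer genes tested; the smaller series alone gave 2073 at 9 h, with 1 residual degree of freedom. At 4 h, 347 higher and 50 lower became 349 and 91 after quantile normalization and 297 and 94 after centring, 1017 and 835 with array weights, 266 and 9 in the larger series alone, 199 and 0 with the contrast's groups alone and 36 and 3 without dim genes. For the moves with no reason given here the cause was not tested.

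Without 1 array, 4 h gave 293 to 1359 genes (highest without control replicate 1; falls 13 to 566, and 14 without 9 h replicate 1) and 9 h 5 to 75 (5 without 9 h replicate 3, 75, 8 and 10 without control replicates 3 and 2 and 9 h replicate 1). At 12 h the range was 6 to 414: 414, 7 and 11 without control replicates 1, 2 and 3, 10, 9 and 11 without the 9 h replicates, 6 and 12 without the 12 h and 7 and 7 without the 15 h replicates. At 15 h it was 6 to 505: 505 and 10 without control replicates 1 and 2, 26 and 33 without 9 h replicates 1 and 2, 29 and 29 without the 12 h and 10 and 6 without the 15 h replicates. At 48 h it was 31 to 104 (31 without 48 h replicate 1, 48 without 9 h replicate 2). For the mean it was 31 to 340: 340 and 31 without control replicates 1 and 2, 82 without 9 h replicate 1, 66 and 68 without the 12 h and 60 and 67 without the 15 h replicates. For 48 h against the mean it was 32 to 502: 446, 502 and 110 without the controls, 82, 83 and 62 without the 9 h, 90 and 79 without the 12 h and 84 and 94 without the 15 h replicates, and 32 without 48 h replicate 1.

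The lists camera called, in the same order, were 12, 16, 13, 16, 16, 11 and 21. With an estimated correlation they were 0 in each of the 7 comparisons. There 0, 4, 4, 3, 4, 5 and 4 lists had an unadjusted p under 0.05. fry called 0, 2, 4, 4, 4, 4 and 7. Without 1 array the ranges were 10 to 14, 9 to 18 (9 without control replicate 2), 11 to 15, 12 to 19, 15 to 23, 9 to 17 (17 without control replicate 2) and 13 to 22 (13 without 48 h replicate 1).

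Reversals among the named genes were all in values that did not pass; among all genes past the threshold at 48 h against control, 74 of 75 kept their sign without the series term. Without the series term Twsg1 was −0.15 at 4 h, 0.24 at 9 h, −0.10 at 12 h, −0.11 at 15 h and −0.31 at 48 h, Hamp 0.040 at 9 h, and Alas2 0.11 at 9 h and −0.068 at 48 h. Twsg1 at 48 h was −0.0098 in the larger series alone and with the contrast's groups alone, −0.0088 after quantile normalization and −0.058 to 0.14 without 1 array. Tfrc at 4 h was 0.011 after quantile normalization and −0.18 to 0.15 without 1 array; Hamp at 9 h was 0 in the smaller series alone and −0.10 to 0.077 without 1 array. Lists reversed without control replicate 2 for globins and red cell membrane at 9 h (−0.17 to 0.030), mitosis at 15 h (−0.22 to 0.0093) and for the mean of 9, 12 and 15 h (−0.18 to 0.020), and erythroid transcription factors for that mean (−0.20 to 0.026), and without 15 h replicate 1 for B-lineage markers at 15 h (−0.23 to 0.053). The mean shift also crossed 0 without control replicate 2, with the call lost and the direction of camera kept, for mitosis (−0.13 to 0.0073) and DNA replication (−0.080 to 0.0093) at 9 h. The cause was not tested.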

Other observations

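The gene lists in this part were written after the called genes had been seen, so their counts and medians describe these arrays and test no direction. The values are for 9, 12 and 15 h together against control. Of 18 cytosolic aminoacyl-tRNA synthetases, which charge transfer RNAs, 4 rose over all genes tested and 15 adjusted over the list alone (median 0.25). Of 8 subunits of CCT, the chaperonin that folds actin and tubulin, 4 rose, Cct3 by 0.44, Cct8 by 0.42, Cct5 by 0.31 and Cct7 by 0.31, and 8 adjusted over the list alone (median 0.31). Of 11 folate one-carbon enzymes, which supply purine and thymidylate synthesis, 3 rose, Mthfd2 by 0.58, Shmt2 by 0.54 and Mthfd1 by 0.54, and 3 adjusted over the list alone (median 0.07). Of 14 proteasome core subunits 2 rose, Psma5 by 0.37 and Psmb7 by 0.34, and 8 adjusted over the list alone (median 0.20).

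Other genes past the threshold at 9 to 15 h, named here after their values were seen, include the cytokine Osm (0.60, adjusted p = 0.0424) and its receptor Osmr (0.68). Cpt1a, which carries fatty acids into mitochondria, fell by 0.54 and Runx1t1 by 0.70. At 48 h against control Plek2 (1.22) and Podxl (0.97, adjusted p = 0.00639) were still past the threshold, and Cish (0.54, adjusted p = 0.207) was not; they too were chosen after their values were seen.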
